A study of Mus musculus with 8 samples.

How the data were processed

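ATAC-seq was carried out on thymic ILC2s of plck-Id1 mice on a C57BL/6 background, transduced with a retrovirus for GFP or for E47-ER and treated with 4-hydroxytamoxifen for 4 or 16 hours, with 2 samples in each of 4 groups. The labels do not say whether the 2 samples of a group came from separate cultures or animals. Groups were taken from the sample titles and are the same in every sample as the transduction and time labels. The free-text sample descriptions name the vector by replicate number in place of by group and were not used.

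Per the submitters' processing notes, cutadapt, Bowtie2, MACS2 and DiffBind were used with genome build mm10; their versions, settings and roles are not given in the sources used here. Per the labels, the deposited tracks of each group were named as trimmed, merged, free of duplicates and mitochondrial reads, Tn5-adjusted and pooled. The deposited files hold 1 peak list per group, named as a conservative set by irreproducible discovery rate, in which peaks are kept for their agreement between replicates. There are no values per sample, so no replicate can be left out. Each line gives a peak's start and end, a summit, a score that the authors' files cap at 1000 and that is never below 540, a fold enrichment (a ratio over local background), and the −log10 of p as the authors gave it; the −log10 of q was not used here. The lowest deposited −log10 p was 2.00 in each list. These values belong to each list alone, grow with depth in the case of −log10 p, and were used only to rank and filter peaks within a list. Read depth per library is not given in the files used here. The number of called regions moves with depth and with the agreement of replicates, so differences in list length limit every comparison.

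Lines of a list that overlapped were merged, which turned 131575, 109772, 112023 and 134423 summit lines (E47 4 h, E47 16 h, GFP 4 h, GFP 16 h) into 49811, 40649, 42665 and 52846 regions on 21 chromosomes. Regions of 2 lists that overlapped by 1 bp or more counted as shared, and regions linked in this way across the 4 lists formed 60835 union regions. Pairs of lists at 1 time were compared in the lists themselves, so these counts differ slightly from those of the union. Strength is the percentile of a region's highest −log10 p in its list, fold is the highest among its peaks, and strong regions are those above percentile 50, the median. Gene positions came from a RefSeq gene table of GRCm38.p6, the same assembly as mm10, with 21900 protein-coding genes. The table gives no strand and no exons, and no genome sequence was used. A planned assignment to the nearest transcription start was therefore replaced by the nearest gene body within 100 kb of the summit, and planned shares of exons and introns and planned motif searches were not run. The nearest gene was found for 95.4% of union regions and is a label of position, not a regulatory assignment.

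Before the data were examined, 14 gene lists were fixed. A few genes are not reported here, and the lists were computed without them. The lists then held 261 genes, of which 260 were in the table. Some genes sit on several lists. For each list, the number of E47-only minus GFP-only regions was set against 10000 random lists, each member that had a region replaced by a gene with the same number of union regions, or by one of the 100 nearest in that number where fewer shared it. The resulting percentile describes these lists and is not a test across replicates. Named genes followed a rule fixed beforehand: the 10 genes with the strongest regions E47-only or GFP-only at both times, the 5 strongest in each list alone, up to 4 members per gene list and direction with the most such regions, and Tcf3, Esr1 and Id1. Other genes, among them Iltifb, Il13, Il17rb and further members of the lists, were chosen after their values were seen, as were the 3 loci drawn.

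Alternatives set beforehand were an overlap of 50% of the shorter region, a gap of 200 bp, lists shortened to equal length, regions above the median of a list only, single summits within 150 bp, autosomes only, and other distances for gene assignment. A stricter score, the nearest gene end, gene lists at equal list length and a list without Il22 were added after the data had been seen. The code was tested on simulated data. All 15 classes of 20000 simulated regions were recovered, 3 of 60 unchanged lists of 20 genes fell outside the middle 95% of random lists, and 44 and 58 of 60 lists with 6 and 10 added regions were found. The simulated regions lay well apart and the simulated genes were independent. Overlaps that chain several regions, shorter lists and lists with neighbouring genes were therefore not covered. Intervals are exact (Clopper-Pearson) at 95%. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.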

Results

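Chromatin accessibility was profiled by ATAC-seq, which maps open chromatin by where the Tn5 transposase inserts, in group 2 innate lymphoid cells (ILC2s) from the thymus of Id1-transgenic mice. Id1 binds E proteins and blocks their activity. The cells carried a retrovirus for GFP alone or for GFP with E47-ER, a fusion of the E protein E47, a product of Tcf3, to a tamoxifen-responsive estrogen receptor part. Transduced cells were sorted for GFP, expanded in cytokines and harvested after 4 or 16 hours of 4-hydroxytamoxifen. The 8 samples formed 4 groups of 2, and each group was represented by 1 peak list that the authors had made from its 2 samples. The lists held 49811 regions for E47 at 4 h, 40649 for E47 at 16 h, 42665 for GFP at 4 h and 52846 for GFP at 16 h. They covered 24.4 Mb, 20.6 Mb, 21.2 Mb and 24.9 Mb in the same order. There was thus no measure of the spread between replicates and no test between groups, and the comparisons below describe these 4 lists. Exact binomial intervals cover counting error only. A region is called E47-only at a time when no region of the GFP list at that time overlapped it, and GFP-only in the reverse case. A region missing from a list was not called there and may still have been accessible below the calling threshold. Regions are given in mm10 and named by the nearest protein-coding gene within 100 kb. Strength is given as the percentile of a region's −log10 p within its own list. Fold enrichment is the authors' value, the highest among the peaks of a region, and belongs to its own list.

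The vector labels were examined at the genes whose coding sequence the constructs add. The sample descriptions named the empty vector for replicate 1 and the E47-ER vector for replicate 2 in all 4 groups, which disagrees with the titles and transduction labels used here. Under the descriptions, every list would pool both vectors, and no comparison below would be one of vectors. At Tcf3 (chromosome 10, 80409541 to 80433976), each of the 4 lists held 1 region, at a gene end, with fold enrichments of 16.7 and 17.4 in E47 and 16.1 and 15.6 in GFP at 4 h and 16 h. At Esr1, the estrogen receptor gene, the lists held 5 and 5 regions in E47 and 6 and 5 in GFP. Id1 carried 1 region in every list, with folds between 9.90 and 13.1. Neither E47 list therefore held more regions over Tcf3 or Esr1 than the GFP list of its time. These counts did not separate the vectors, and since exons were not distinguished they settle neither reading of the labels.

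Which regions set E47 cells apart from GFP cells at both times was asked first. The E47-only regions with the highest strength included those named for Prps1l1, Ppm1h, Oxsm, Snrpe, B4galt1, Chrna9, Sag, Cpn2 and Rpl11. The region 4078 bp from Prps1l1 (chromosome 12, 34990198 to 34990947) ranked first, at a mean percentile of 81.5 over the 2 lists and folds of 20.4 and 16.5. B4galt1, a galactosyltransferase gene, held its region inside the gene with folds of 13.1 and 12.4, whereas the regions named for Oxsm and Snrpe lay 65104 bp and 53841 bp from the gene.

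The strongest regions called in both GFP lists and in neither E47 list included those named for Rgs21, Slc35d1, Polr3b, Ttc27, Dnah3, Ap3s2, Fcgr1, Fli1 and Garre1. The region near Rgs21 (chromosome 1, 144436567 to 144437333) had folds of 16.7 at 4 h and 19.7 at 16 h and a mean percentile of 73.6. The one 6074 bp from Fli1, an ETS-family transcription factor gene of blood cells, had folds of 12.3 and 14.8. Fli1 also held 2 weaker regions inside the gene that were E47-only at both times.

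In all, 2088 regions were E47-only at both times and 2776 were GFP-only at both times, out of 60835 regions in the union of the lists, of which 29667 (48.8%) were in all 4 lists. The other ways of pairing the lists served as background. Only 781 regions were called in both 4 h lists and neither 16 h list, and 656 in both 16 h lists and neither 4 h list. A further 2780 regions were in E47 at 4 h and GFP at 16 h, the 2 longest lists, and 203 in the 2 shortest. Regions separated by transduction were thus 3.38 times as many as those separated by time, a comparison in which each pair joins a longer and a shorter list. With all lists shortened to 40649 regions by −log10 p, 2387 regions were E47-only and 2523 GFP-only at both times, 680 and 461 were separated by time, and 653 and 572 were in the remaining pairs. Among regions above the median −log10 p of both of their lists, 115 were E47-only at both times (5.51% of that class; 95% exact binomial interval 4.57 to 6.57) and 51 were GFP-only (1.84%; 1.37 to 2.41), against 2 and 0 separated by time. The excess of GFP-only over E47-only regions in the full lists was thus turned round among strong regions.

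**Figure D1:**
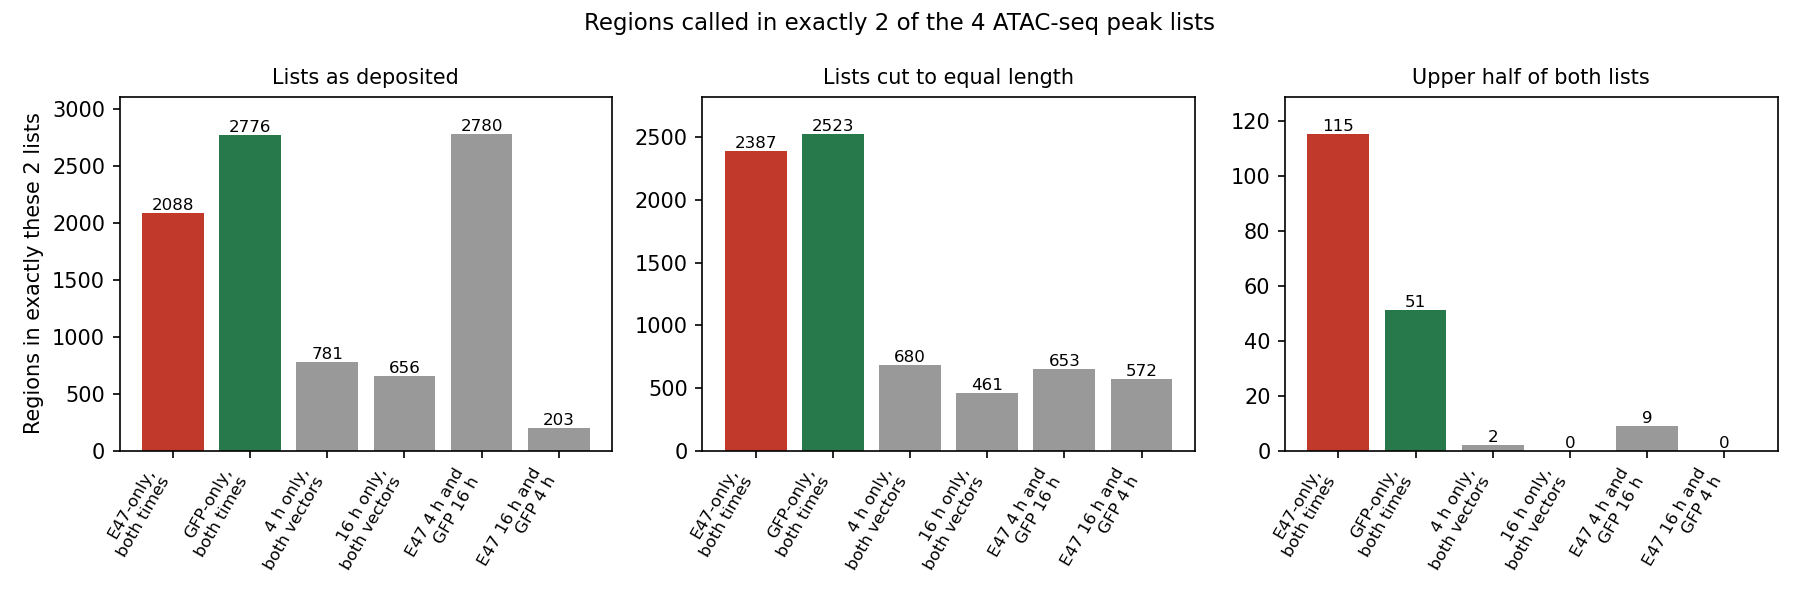
Number of regions called in exactly 2 of the 4 lists, for the lists as deposited, shortened to equal length, and limited to regions above the median −log10 p of both lists. Bars for E47-only (red; 2088, 2387 and 115) and GFP-only regions (green; 2776, 2523 and 51) stand above those separated by time (781 and 656 at full length) in each panel, while the bar for E47 4 h with GFP 16 h falls from 2780 to 653 at equal length.

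Genes typical of group 3 innate lymphoid cells (ILC3s) and Th17 cells had E47-only regions at both times more often than GFP-only ones. Of the 11 members of this list, 6 had a region that was E47-only at both times (Il22, Il17a, Il17f, Il23r, Lta and Lif), 1 had a GFP-only region (Il1r1), and Ccr6, Ltb, Ncoa7 and Batf3 had neither. The net of 7 E47-only against 1 GFP-only regions lay at percentile 99.91 of 10000 random gene lists matched on the number of regions per gene, whose middle 95% ran from -5 to 3. Il22, which encodes interleukin 22, had its region 6125 bp from the gene (chromosome 10, 118216017 to 118216822) with folds of 12.5 and 15.4. A like region lay 6371 bp from Iltifb, the near-identical copy of Il22, so reads could be shared between both genes and either region is uncertain. The neighbouring genes Il17a and Il17f, which encode the Th17 cytokines interleukin 17A and 17F, each had 1 region, with folds of 9.45 and 8.64 for Il17a and 11.5 and 10.1 for Il17f. Both regions lay between these genes, so 1 locus counted as 2 members. Genes of the random lists were drawn independently, so the percentile of 99.91 may be too high. Il23r, the interleukin 23 receptor gene, held its region inside the gene with folds of 8.25 and 7.92. With regions limited to genes and 5 kb to either side, the net was 2 and the percentile 91.16, inside the middle 95% of random lists. With regions above the median of both lists only, the net was 1, from Il22, and the percentile 96.42, also inside.

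**Figure D2:**
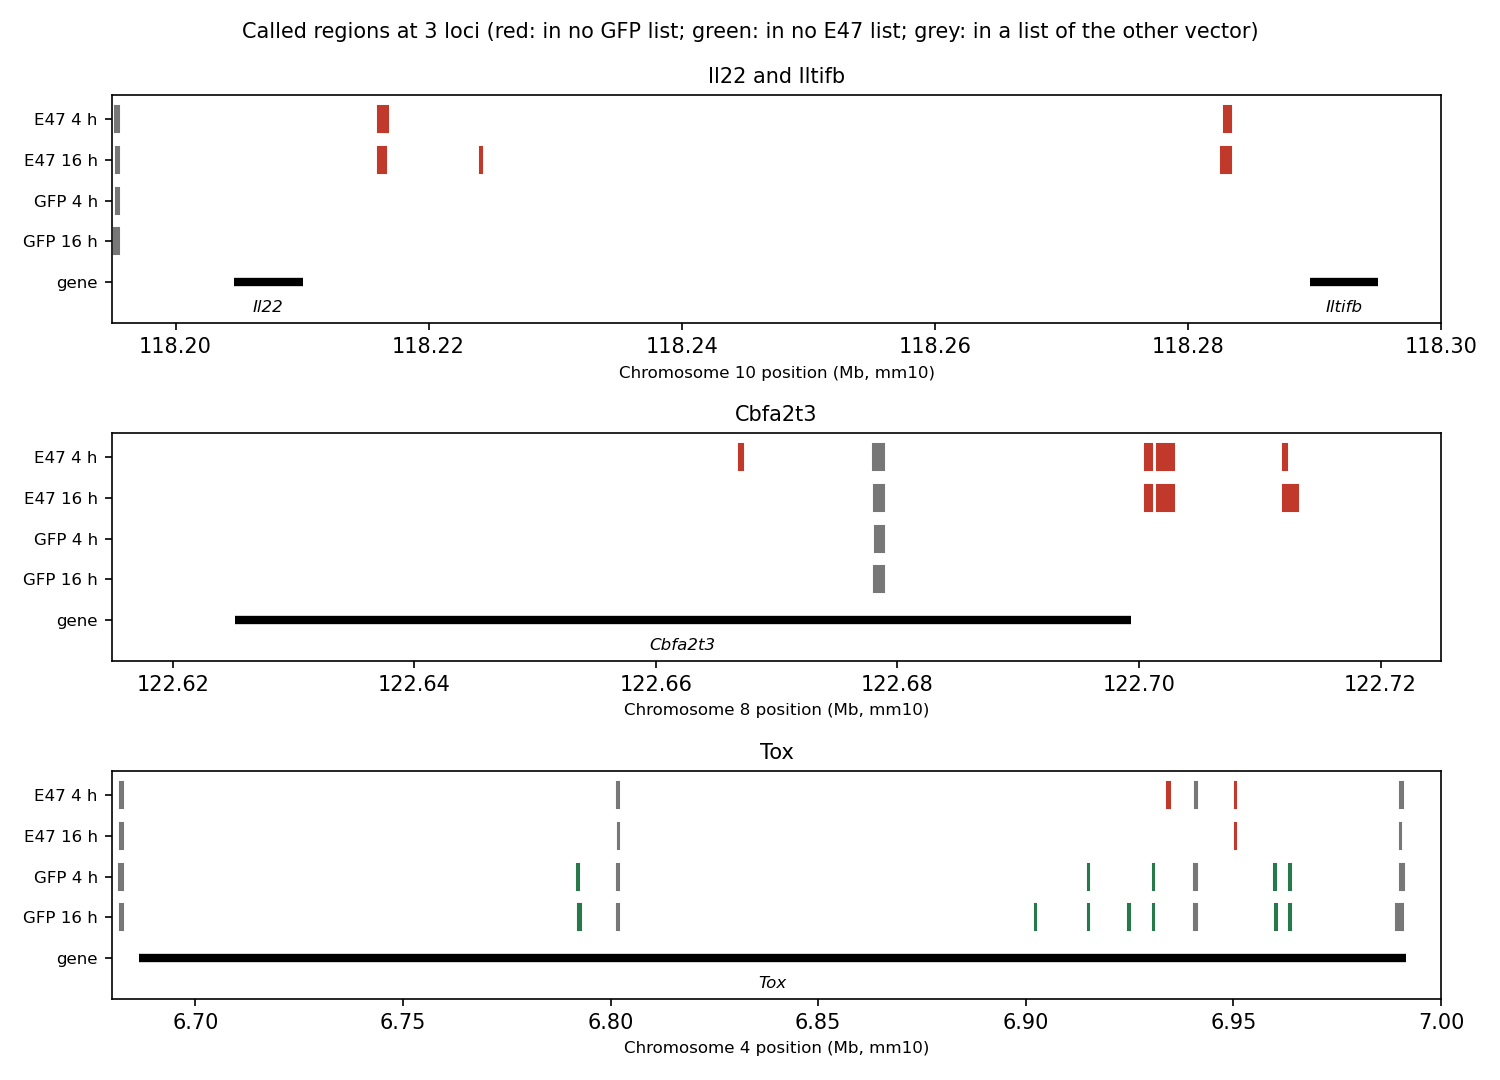
Called regions at Il22 with Iltifb, Cbfa2t3 and Tox in the 4 lists against mm10 position in Mb, with gene bodies as black bars. Red regions overlapped no GFP region, green ones no E47 region, and grey ones overlapped a region of the other vector. The region at 118216017 to 118216822 beside Il22 is in both E47 lists and no GFP list, and 5 regions of Tox are in both GFP lists and no E47 list.

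Genes known to be bound or controlled by E proteins, and transcriptional repressors with the AP-1 family, showed the same direction without leaving the range of random lists. Among the first, 29 of 35 members had a region in any list. Of the 35, 12 had an E47-only region at both times and 10 a GFP-only region, with 18 against 11 regions (percentile 95.5). Among the repressors, 8 of 29 members had an E47-only and 6 a GFP-only region, with 14 against 7 regions (percentile 96.92). Cbfa2t3, which encodes the corepressor ETO2 and sits on both lists, held 3 E47-only regions beyond one end of the gene out of 5 regions in all. The strongest (chromosome 8, 122701522 to 122702907) had folds of 6.43 and 6.77. Jdp2, an AP-1 repressor gene that is also on both lists, had 2 E47-only regions and 1 GFP-only region. The regions of Cbfa2t3 and Jdp2 count in both lists, so the shared direction is partly due to the same regions. Ikzf1, the Ikaros gene, had 3 E47-only regions. Socs3, a feedback inhibitor of cytokine signalling, had 2, the stronger 13677 bp from the gene with folds of 9.94 and 9.17. Foxo1 also had 2. On the list of E proteins, Id proteins and partners, Cbfa2t3, Id3 and Id4 had E47-only regions and Tcf12 and Tal1 had GFP-only ones (percentile 86.52).

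T cell and cytokine receptor genes were divided. Of 35 T cell members, 28 of which had a region in any list, 11 had an E47-only and 10 a GFP-only region at both times (16 against 14 regions, percentile 81.6). Dntt, which encodes terminal deoxynucleotidyl transferase, held 2 E47-only regions inside the gene, the stronger (chromosome 19, 41039117 to 41039689) with folds of 13.6 and 12.7. Hes1, a Notch target gene, also had 2, at 83679 bp and 78009 bp, and Tcf7, the TCF-1 gene, 1, whereas Notch1 and Notch3 each had 2 GFP-only regions. Of 33 cytokine receptor and JAK-STAT members, 8 had an E47-only and 8 a GFP-only region (14 against 9 regions, percentile 93.88). Tgfbr2, the type II receptor of TGF-β, had 4 E47-only regions among 31, and Jak1 had 2, with 1 GFP-only. Il2ra, Il7r, Il4ra and Il1rl1, which encode receptor chains for interleukin 2, interleukin 7, interleukin 4 and interleukin 33, had GFP-only and no E47-only regions at both times. Il7r, Il4ra and Il1rl1 had only 1 such region each, and these were weak. Their percentiles at 4 h and 16 h were 11.8 and 15.3 for Il7r, 23.8 and 32.3 for Il4ra, and 14.9 and 29.7 for Il1rl1. The Il7r region lay 19343 bp from the gene.

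ILC2 genes did not stand apart. Of 28 ILC2 identity and effector genes, 5 had an E47-only and 11 a GFP-only region at both times (8 against 14 regions), a net of -6 at percentile 29.15 of random lists. Those with GFP-only regions included Gata3, the main ILC2 transcription factor, with 1 weak region 53962 bp from the gene, Areg, the amphiregulin gene, with 2, and Il2ra with 2. Rora, which encodes RORα and is needed for ILC2 development, had 3 E47-only regions and 1 GFP-only region among 29. All 6 regions of Il13, an ILC2 effector cytokine gene, were in all lists, and so was the 1 region of Il17rb, the interleukin 25 receptor gene. Of 14 innate lymphoid precursor regulators, 4 had an E47-only and 5 a GFP-only region (5 against 11 regions, percentile 13.98). Tox, a regulator of innate lymphoid precursors, accounted for 5 of those 11, all inside the gene, beside 1 E47-only region. Its strongest (chromosome 4, 6963512 to 6963956) had folds of 11.3 at 4 h and 12.2 at 16 h. Maf had 3 GFP-only regions.

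Among lists for other cell types, the myeloid and dendritic cell genes had 5 E47-only against 1 GFP-only regions. Their net of 4 lay on the edge of the random range of -6 to 4 and passed the limit only by its percentile of 97.96. The E47-only regions were at Irf8, Itgam, Cebpe and Cebpb, none of them above the median of both lists. With regions limited to genes and 5 kb to either side, this was the only list outside (percentile 99.46), while at equal list length it fell to percentile 81.96. B cell genes had 0 against 2 regions (percentile 6.97), mast cell and basophil genes 0 against 3, all at Mitf (percentile 6.24), and NK, ILC1 and cytotoxic genes 1 against 1 (percentile 60.05). Cell cycle and survival genes had 7 against 9 regions (percentile 51.45), with Mcl1, an anti-apoptotic gene, having 1 of each. Housekeeping genes had 0 against 4, 3 of them named for Ywhaz and 1 inside Hprt (percentile 8.98). Over 14 lists and 3 contrasts, 8 of 42 values lay outside the middle 95% of random lists by percentile, where 2.1 would be expected by chance. The values are not independent, so the spread around that number is not known.

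**Figure D3:**
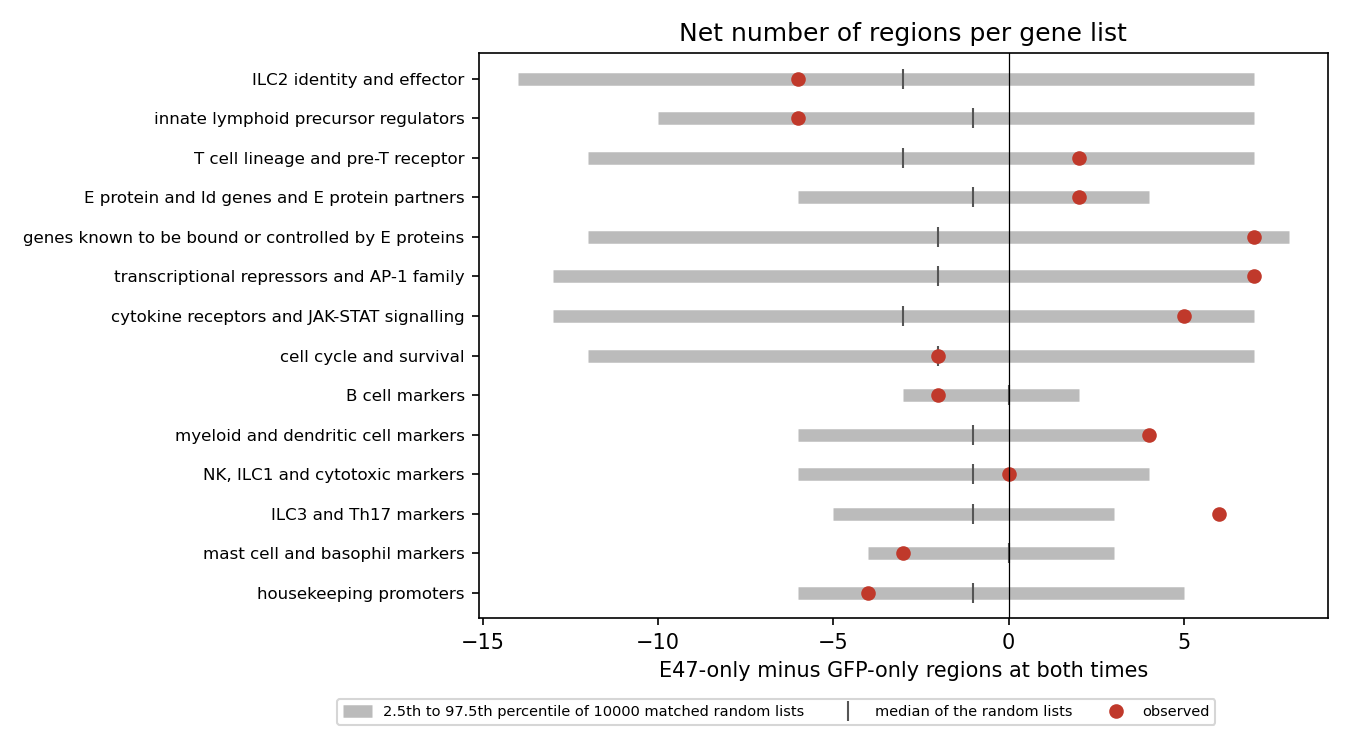
E47-only minus GFP-only regions at both times for the 14 gene lists (red points), with the middle 95% (grey bars) and median (ticks) of 10000 matched random lists. The ILC3 and Th17 point, at 6, lies beyond its random range of -5 to 3.

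At 4 h alone, the E47 list, the longer of the 2, had more regions of its own than the GFP list. Of the E47 list, 12405 regions (24.9%; 24.5 to 25.3) were E47-only, and of the GFP list, 5272 (12.4%; 12.05 to 12.7) were GFP-only. Of the 11 ILC3 and Th17 genes, 10 had an E47-only region at 4 h and 2 a GFP-only region (percentile 99.52). At percentiles of 8.42 and 51.43, the ILC2 and T cell lists lay inside the random range. The strongest regions called in E47 at 4 h and in no other list were named for Camk1g, Wdr95, Tnik, Ccdc171 and Cdk19, with percentiles of 50.8 to 57.8. For GFP at 4 h they were Sugct, Slc1a4, Fkbp9, Ccdc146 and Nfia, at 38.4 to 46.96. Regions called by one vector were weak, with a median percentile of 17.4 for E47-only against 62.2 for shared regions, and 13.8 against 56.1 in GFP. None lay above percentile 90 of its list.

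At 16 h, where the GFP list was the longer, the counts lay the other way. GFP had 16676 regions of its own (31.6%; 31.2 to 31.95) and E47 had 4799 (11.8%; 11.5 to 12.1). With list lengths made equal, the counts were 7831 and 7660 at 16 h, and 6234 and 6394 at 4 h. Relative to random lists, the T cell list (32 E47-only against 51 GFP-only regions, percentile 99.6), the repressor and AP-1 list (25 against 53, 98.67), the cytokine receptor list (25 against 53, 97.79) and the ILC3 and Th17 list (10 against 11, 98.17) had a higher net of E47-only minus GFP-only regions, though each net was below 0. B cell genes had a lower net (1 against 10, 1.54). Whether E47-only or GFP-only regions made these differences was not tested. The gene lists at 4 h alone and at 16 h alone were not rerun at equal list length or in any other alternative setting. The strongest regions called in E47 at 16 h alone included those named for Nme7, Dctd, Zcwpw2 and Prdm1. Prdm1 encodes the transcriptional repressor Blimp-1, and its region, 87209 bp from the gene, had a fold of 12.2. Those in GFP at 16 h alone were named for Pex7, Eml4, Manba, Nampt and Slc25a15, at percentiles of 62.1 to 66.5.

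How E47-only regions behaved over time was then followed in the union of the lists. Of 11861 regions E47-only at 4 h, 2088 (17.6%; 16.9 to 18.3) were still E47-only at 16 h, 2607 (22.0%) were in both 16 h lists, 2780 (23.4%) in GFP alone and 4386 (37.0%) in neither. Of 4553 regions E47-only at 16 h, 45.9% (44.4 to 47.3) had been E47-only at 4 h, 19.2% in both 4 h lists, 4.46% in GFP alone and 30.5% in neither. Of 5093 regions GFP-only at 4 h, 54.5% (53.1 to 55.9) were GFP-only at 16 h. In the other direction, 17.3% (16.7 to 17.9) of 16071 regions GFP-only at 16 h had been GFP-only at 4 h. These shares depend on the length of the 4 lists. Between times within a vector, E47 had 12601 regions at 4 h that were not called at 16 h and 3141 the other way, while GFP had 3421 and 13081.

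Regions set apart by the vector lay away from gene ends. A summit within 1 kb of an end of a protein-coding gene was found for 36.8% (36.3 to 37.4) of regions in all lists, 10.5% (9.21 to 11.9) of those E47-only at both times and 6.20% (5.33 to 7.16) of those GFP-only at both times. For regions separated by time, the share was 17.5% (14.9 to 20.4) at 4 h and 13.7% (11.2 to 16.6) at 16 h. Summits inside genes and over 1 kb from their ends made up 53.0% of E47-only, 53.8% of GFP-only and 37.6% of regions in all lists.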

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

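The tests of the strength of regions, of cultures before tamoxifen, of mature T cells and of ILC3-like cells were chosen only after the result was seen.

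The balance of regions called by one vector turned between the times. E47-only minus GFP-only regions came to 7133 at 4 h and to -11877 at 16 h, 2780 regions were in E47 at 4 h and GFP at 16 h alone, and 203 were in E47 at 16 h and GFP at 4 h alone. The difference between the times was not tested, since each group had 1 list. The turn of the balance is nearly the same quantity as the difference in list length, so length is not a separate explanation of it. Overlapping regions were nearly equal in number in the 2 lists of a time: 37406 (E47) and 37393 (GFP) at 4 h, 35850 and 36170 at 16 h. What made the lists differ in length was not tested, and read depth or an effect of E47 on accessibility could each do so. List length may account for the crossed pairs. With lists shortened to equal length, their regions were 1.074 times as many as those separated by time. Only 0.324% of the 2780 regions lay above the median of both lists, below the 5.51% and 1.84% of the classes separated by vector. The classes separated by time were about as weak (0.256% of 781 regions and 0% of 656), so this share does not single out list length. The balance turned also among regions above the median of their list (530 at 4 h, -1563 at 16 h) and at the highest score (1948 and -4149), which list length allows as well, since each was set against the whole of a longer or shorter list. An E47 effect that changes between 4 h and 16 h stays open as untested, for single regions and for the number of regions called.

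Regions separated by vector outnumbered those separated by time. List length does not account for this, since the ratio was 4.303 at equal length against 3.38 in the full lists. A difference between the cultures before tamoxifen cannot be told apart from an effect of E47-ER activity, because cells without tamoxifen were not analysed here. Of 220 regions E47-only at 16 h and above the median of that list, 66.8% (60.2 to 73.0) were already E47-only at 4 h, which either explanation allows.

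ILC3 and Th17 genes had a higher net of E47-only minus GFP-only regions than most matched random lists. They were not alone in this: the myeloid and dendritic cell genes passed the limit by percentile (97.96), with a net of 4 on the edge of their random range. With genes and 5 kb to either side, the myeloid genes lay outside (99.46) and the ILC3 and Th17 genes did not (91.16). Mature T cells in the E47 cultures would bring open T cell receptor and co-receptor genes, but 12 such genes, 8 of them with a region in any list, had a net of -3 regions and 0 E47-only ones, and Cd4 and Cd8a had no region assigned in any list. Reads shared between Il22 and Iltifb are not the whole source, since Il22 gave only 1 of the 7 E47-only regions. Without it the net was 5 (percentile 99.83). Leaving out 1 region could hardly bring the net into the random range of -5 to 3, so this does not bear on the Il22 region itself. An outgrowth of ILC3-like cells may also give E47-only regions at 6 of the 11 genes and cannot be told apart from a change within the ILC2s, since the lists average over cells. A change made by E47-ER in these cells stays open as a hypothesis, and the sort for GFP would remove neither cell type.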

How the results depend on the processing

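No paired analysis was possible because the files hold 1 list per group, and for the same reason no replicate was left out. The stricter score, the nearest gene end, the gene lists at equal list length and the list without Il22 were chosen after seeing the data. The motif alternatives were not run, as no sequence was used. An overlap of 50% of the shorter region, a gap of 200 bp and autosomes only moved no count of E47-only or GFP-only regions, nor their difference, by over 1.5 times. At equal list length, E47-only regions were 6394 at 4 h and 7660 at 16 h, and GFP-only regions were 7831 at 16 h. E47-only minus GFP-only came to 160 at 4 h, -171 at 16 h and -136 at both times. Near-zero differences at a single time follow from the equal lengths, which do not fix the difference at both times. Among regions above the median of a list, E47-only and GFP-only counts were 628 and 98 at 4 h (530), 223 and 1786 at 16 h (-1563), and 115 and 51 at both times, a difference of 64 that reversed the direction. The highest score was held by 64.1% to 65.7% of the regions of each list, so this setting kept more regions than the median did. With it, they were 2623 and 675 at 4 h (1948), 777 and 4926 at 16 h (-4149), and 333 and 314 at both times, reversed to 19. The cause of the reversals was not tested. Counting single summits gave 31949 and 13587 at 4 h (18362), 14402 and 38199 at 16 h (-23797), and 6117 and 6282 at both times (-165). Gene lists were rerun only for regions at both times, where 2 lay outside the middle 95% of random lists by percentile. The net of the myeloid list, 1 of these, was on the edge of its range. With genes and 5 kb to either side 1 did, the myeloid list (99.46), and above the median 0 did. ILC3 and Th17 genes had a net of 2 (percentile 91.16) in the first of these and of 1 (96.42) in the second, where fewer regions counted, and their call was lost in both. It held in the other settings, at percentiles of 99.11 to 99.86. The list of E protein targets lay outside with genes within 20 kb (98.23) and, barely, at equal list length (97.51). The myeloid list also held within 20 kb (98.8) and by nearest gene end (97.65), and lay inside above the median (48.12) and at equal list length (81.96). Of the values for single gene lists, for time within a vector and for the other pairings of lists, 88 stayed on their side of the limit or within 1.5 times, and 29 moved. Depth limits all of this: regions called by one vector were mostly weak, and absence from a list is not closed chromatin.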

Other observations

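The genes named here were chosen after the data were seen. Several regions E47-only at both times gathered at single genes outside the fixed lists. Mgat5, which encodes a branching N-glycan transferase, held 8 of its 32 regions in this class, all inside the gene, and Itpr2, an inositol trisphosphate receptor gene, 6 of 35, beside 2 GFP-only ones. Ppm1h, a phosphatase gene, had 6 of 34, of which 3 lay above the median of both lists, beside 2 GFP-only ones. Sla, which encodes the adaptor SLAP, a regulator of antigen receptor signalling, had 5 of 15, all inside the gene. Ccr9, the receptor for the thymic and gut chemokine CCL25, had 2 of its 3 regions E47-only at both times, the stronger (chromosome 9, 123754199 to 123754818) with folds of 12.7 at 4 h and 13.6 at 16 h. Long genes hold more regions, so such counts are not tests.

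On the GFP side, Bbs9 had 6 of 24 regions GFP-only at both times and the raft protein gene Rftn1 5 of 37. Alpk2 had 5 of 12 and Nek7 5 of 26, each of these beside 1 E47-only region. The phosphodiesterase gene Pde4d had 5 of 46, beside 2 E47-only ones, and Elmo1, a regulator of Rac signalling, 5 of 48, beside 1. Among the regions in E47 at 4 h and GFP at 16 h alone, Etv6, an ETS-family repressor gene, had 7 of 37, and Zmiz1 had 5 of 48.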
